A study of Caenorhabditis elegans with 4 samples.

How the data were processed

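ChIP-seq peak lists of GFP-tagged LIN-15B in whole L4 larvae of mixed sex were analysed, from 4 samples in 1 group. Per the labels, replicates 1 and 2 are single libraries and replicate 3 has 2 technical libraries, which the deposited lists treat as 1 alignment and which were counted once. The replicates are labelled biological, with no further detail of how the cultures were kept apart. Per the deposited descriptions, peaks were called for each replicate and for the pool of all 3, each against a control alignment, and were kept with background as input to a test of reproducibility between replicates (irreproducible discovery rate, IDR), whose result is the optimal list. The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here. Lists exist on 2 builds, ce10 and ce11, and ce11 was used for the main results.

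The deposited lists give a score for each peak, the authors' signal value, which was used only to rank or filter peaks within a list. They also give the −log10 of the q-value, deposited by the authors, between 0.699 and 1.49 for the optimal peaks, which was not used for ranking. The columns that hold a constant were not used. Replicate lists hold 30000 peaks each, so they reach far into background. No counts are given, and the depth of each sample is unknown, so the precision it gives could not be compared between replicates. Intervals given for shares of peaks or genes cover counting error only, and peaks and genes are not replicates. The replicate error is therefore given as the SD over the 3 replicate lists, from the 383 highest-scoring peaks of each against the rest of the same list.

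Candidate peaks were the 8232 pooled peaks that overlap no optimal peak by 1 bp or more; 21 pooled peaks that overlap one were left out. The annotation was Ensembl release 115 on the WBcel235 assembly, which has the coordinates of ce11, and sequence came from the same assembly. A promoter peak has its summit within 500 bp upstream to 100 bp downstream of a protein-coding transcript start. Recovery is the share of optimal summits inside the 383 highest-scoring peaks of a replicate. Pairwise overlap needs at least 1 bp and is averaged over both directions of a pair. Chance values come from 100 random placements on the same chromosome. Chromosome centres lie between 1/3 and 2/3 of the length, and mitochondrial peaks were left out of the X and centre comparisons.

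For gene lists the background was genes with any pooled peak in the promoter window, 2493 protein-coding genes of which 395 had an optimal peak, plus microRNA or tRNA genes for those lists. There were 26 lists, and 4 of their symbols (rad-54, cde-1, prg-2 and opt-2) were not found in the annotation. Lists matched by a pattern of gene names could not be checked for missing members. MicroRNA names carry a species prefix in the annotation, which was removed before matching. The list of transgene loci (lin-15B and unc-119) had 0 of 1 bound. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists or over the 10 motifs and a threshold of 0.05; the promoter, X and centre tests were not adjusted. G+C content was compared by a permutation test with 100000 resamples. Odds ratios stratified by G+C content used Mantel-Haenszel tables in bins of 5 percent, in place of drawing a matched background.

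Named genes follow a rule set before the data were examined: the nearest protein-coding gene within 1000 bp, or both genes of a divergent promoter, for the 20 optimal peaks with the highest score; the members of each fixed list with an optimal peak, all where there are 5 or fewer and otherwise the 5 with the highest score; and lin-15B, lin-15A and unc-119. Mitochondrial genes, and genes named for sharing a peak with a listed or snoRNA gene, were chosen after their values were seen. The lists, motifs, tests and most alternatives were also set before the data were examined.

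The tests were tested on simulated data of the same sizes. With no list enriched, 0 of 100 draws of 395 from 2493 genes called any list. Genes were drawn singly, not in the pairs that share a divergent promoter, and the microRNA and tRNA lists were left out of these draws. With ribosomal protein genes given 3 times the weight, 91 of 100 draws called that list, and with the smaller synMuv and chromatin list 29 of 100. At 8 times the weight both were called in 100 of 100. For motifs, 5 of 100 random sets called any motif, and an E2F element added to 10 percent of windows was called in 100 of 100. For G+C content, 0 of 20 unchanged sets and 20 of 20 sets with 3 points added passed. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

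Alternatives were the ce10 lists, the upper 50 percent of the optimal peaks by score (the lists give no IDR value to tighten), each replicate left out in turn by keeping only optimal peaks found in the top-ranked peaks of both others, other overlap rules, promoter windows, sequence windows and backgrounds. A replicate left out in this way still took part in the pooled list, so independence from it was not tested. The centre comparison on ce10 was not run, since chromosome lengths of that build were not used here.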

Results

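Chromatin immunoprecipitation followed by sequencing was used to map where LIN-15B sits in the genome of Caenorhabditis elegans L4 larvae. LIN-15B is a nuclear THAP-domain protein of the synMuv B class, genes first known from vulval development and later from the repression of germline genes in somatic tissue. It was carried as a GFP fusion on a transgene, and whole larvae of mixed sex were used. The 4 samples form 1 group with 3 biological replicates, and replicate 3 consists of 2 technical libraries that share 1 peak list. There was no second condition, so the comparisons are between replicates and between the peaks that passed the authors' reproducibility threshold (optimal peaks) and the remaining peaks of the pooled list (candidate peaks). The lists hold no read counts, so the sequencing depth of each sample is unknown.

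LIN-15B peaks that passed the threshold numbered 383 on the ce11 assembly, and several of the strongest nuclear ones lay just upstream of ribosomal protein genes. The pooled list held 8636 peaks, and the optimal peaks were its 383 highest-scoring ones. The highest nuclear score, 385.4, was at chromosome II 10563448 to 10563703, an intergenic site whose summit lay 178 bp upstream of cdc-48.1, which encodes an AAA ATPase that extracts ubiquitinated proteins. The peak at III 10759096 to 10759385 (score 338.6) was intergenic, 60 bp upstream of tasp-1. An intergenic peak at IV 4749940 to 4750207 (score 338.0) lay between the divergent genes Y17G9B.5 and rpl-20, 175 and 287 bp upstream of their starts. The next nuclear peaks were upstream of rpl-3 (score 298.9), the translation factor gene iff-2 (210.6) and rpl-35 (210.3). The peak at III 5679025 to 5679242 (197.6) was shared by ska-3 and rps-12, and that at IV 13240564 to 13240769 (185.4) by rpl-12 and lin-54, a gene of the DREAM complex. Others among the 20 highest scores lay upstream of ntl-11, eelo-2, scc-2 and wwp-1, or between the divergent pairs rpl-15 and K11H12.8, ndk-1 and F25H2.6, ekl-4 and rps-20, and set-16 and drr-2. Each of the 16 nuclear peaks among these 20 was also inside a top-ranked peak of all 3 replicates.

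Mitochondrial DNA held the highest score of all, 408.4 at 4612 to 4951, within the coding sequence of the cytochrome b gene. In total 18 optimal peaks were mitochondrial. The replicate lists of 30000 peaks each held 20, 0 and 29 mitochondrial peaks in replicates 1, 2 and 3, so replicate 2 had none of them, and they were left out of the comparisons between nuclear chromosomes.

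The replicates recovered most optimal peaks among their own strongest peaks. The summit of an optimal peak lay inside one of the 383 highest-scoring peaks for 60.6% (95% Wilson interval 55.6 to 65.3) of optimal peaks in replicate 1, 64.8% (59.8 to 69.4) in replicate 2 and 70.0% (65.2 to 74.3) in replicate 3, a mean of 65.1% ± 4.71 (SD, n = 3). Random placement on the same chromosomes gave 0.132%, 0.178% and 0.151% for the nuclear peaks. The observed shares include mitochondrial optimal peaks, none of which replicate 2 could recover. Among the nuclear optimal peaks alone they were 59.7%, 67.9% and 69.0% in replicates 1, 2 and 3. All 3 replicates shared 130 of the optimal peaks at this rank, a further 127 were in exactly 2 and 22 in none. In the full lists of 30000 peaks, 94.3%, 94.5% and 97.9% of optimal summits were covered, and 95.1%, 99.2% and 98.4% of the nuclear ones. A single random placement of these lists covered 10.1%, 7.40% and 12.6% of the nuclear optimal summits. Because the optimal peaks came from a pool that includes each replicate, recovery is not an independent test.

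Direct comparison of the replicates gave lower overlap. Of the 383 highest-scoring peaks, 44.9% were shared between replicates 1 and 2, 50.4% between 1 and 3 and 47.9% between 2 and 3, with a mean of 47.7% ± 2.75 (SD over the 3 pairs). Random placement gave 0.313%, 0.305% and 0.253% for the nuclear peaks. The observed shares include mitochondrial peaks, of which the top-ranked peaks held 19, 0 and 27 in replicates 1, 2 and 3. These could be shared only between replicates 1 and 3. Across the optimal nuclear peaks found in both lists of a pair, Spearman's rho of the scores was 0.494, 0.438 and 0.474 in the same order, over 344, 342 and 356 peaks, which are not independent replicates.

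Optimal peaks were promoter peaks. A summit within 500 bp upstream to 100 bp downstream of a protein-coding transcript start was found for 284 of 383 optimal peaks (74.2%, 95% Wilson interval 69.5 to 78.3) and 1926 of 8232 candidate peaks (23.4%). The odds ratio was 9.39 (Fisher's exact test, two-sided, p = 2.38e-92). The top-ranked peaks of the replicates gave the same direction in 3 of 3, with 65.4% ± 1.66 (SD, n = 3) against 17.5% ± 0.492 in the rest of each list. Among optimal nuclear peaks with a start within 1000 bp, the median summit position was -181.5 bp relative to the start, and 95.5% lay upstream of it, against 55.8% of the 4072 candidates with such a start. Intergenic sequence held 75.2% of optimal and 38.1% of candidate summits, coding exons 4.44% and 21.1%, and introns 8.62% and 29.2%. These shares and the promoter share count the 18 mitochondrial optimal peaks, while 0 candidate peaks were mitochondrial. Most of the optimal summits in coding exons were mitochondrial, and some mitochondrial peaks counted as promoter peaks. Of the promoter peaks, 110 of 284 optimal (38.7%) and 259 of 1926 candidate (13.4%) stood between starts on opposite strands (odds ratio 4.07, Fisher's exact test, two-sided, p = 3.79e-22).

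**Figure D1:**
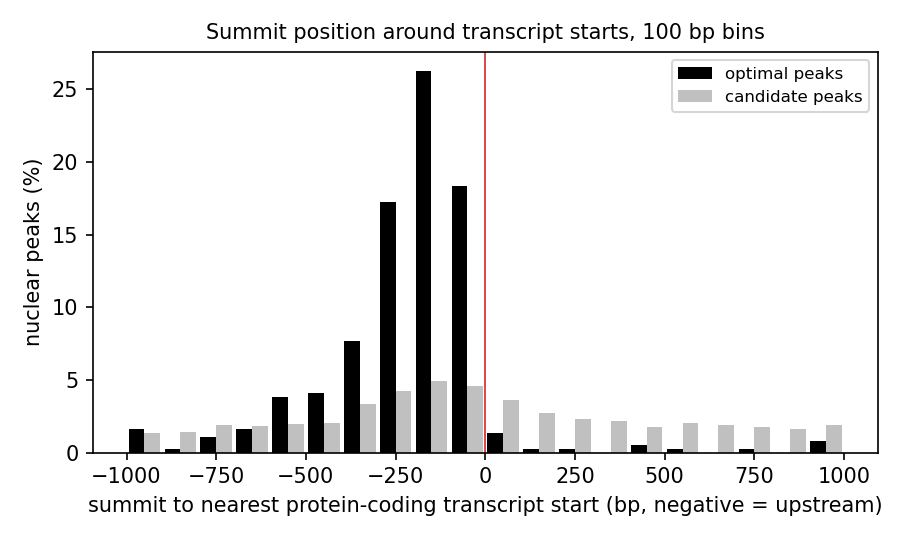
Share of nuclear optimal peaks (black) and candidate peaks (grey) by the distance in bp from the summit to the nearest protein-coding transcript start, in 100 bp bins; the red line marks the start and negative values are upstream. Optimal summits pile up upstream of the start, with a median of -181.5 bp, while candidates are spread over both sides, with a median of -66 bp. The medians cover only peaks with a start within 1000 bp, 314 of 365 optimal and 4072 of 8232 candidate peaks.

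The X chromosome was poor in optimal peaks. It held 33 of 365 nuclear optimal peaks (9.04%, 95% Wilson interval 6.51 to 12.4) and 1448 of 8232 candidate peaks (17.6%), an odds ratio of 0.466 (Fisher's exact test, two-sided, p = 7.18e-06). The top-ranked peaks of the replicates gave 10.2% ± 0.998 (SD, n = 3), lower than the rest of the list in 3 of 3. Chromosomes I and III had the largest numbers, 80 and 75, while the largest nuclear chromosome, V, had 54. Among promoter peaks alone the X share was 3.99% for optimal and 11.5% for candidate peaks (Fisher's exact test, two-sided, p = 3.78e-05).

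The middle of the chromosomes, between 1/3 and 2/3 of their length and rich in conserved genes, held 126 of 365 nuclear optimal peaks (34.5%, 95% Wilson interval 29.8 to 39.5) and 43.0% of candidate peaks (odds ratio 0.699, Fisher's exact test, two-sided, p = 0.00139). Against random positions, of which 33.0% were central, the optimal peaks did not differ and lay to the other side (odds ratio 1.07, Fisher's exact test, two-sided, p = 0.56). The top-ranked peaks of the replicates gave 35.6% ± 0.467 (SD, n = 3) against 38.2% ± 0.596 in the rest of each list, lower in 3 of 3. In no single replicate did the difference pass (Fisher's exact test, two-sided, p = 0.256, 0.397 and 0.35).

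Ribosomal protein genes were the gene group most often bound. Of the 59 with any pooled peak in the promoter window, 35 had an optimal one (59.3%, 95% Wilson interval 46.6 to 70.9), against 14.8% of other genes in the background. The odds ratio was 8.40 (Fisher's exact test, two-sided, adjusted p = 3.71e-13 over 26 lists). The highest scores were at rpl-20, rpl-3, rpl-35, rps-12 and rpl-12, and for 15 of the 35 genes the peak was top-ranked in all 3 replicates. The top-ranked peaks of single replicates covered 28, 29 and 24 of the 78 annotated members, a mean of 34.6% ± 3.39 (SD, n = 3), where 1.70% ± 0.0247 of all protein-coding genes were covered. The list stayed past the threshold under every alternative tried, with odds ratios from 4.62 with the nearest start alone (21 of 59 bound) to 44.2 against all annotated genes. Without replicate 2 it was 4.63 (16 bound) and against the upper 50 percent of the candidates 5.35.

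Translation factor, mitochondrial and chaperone genes passed the test by less. Translation factor genes had 8 of 21 bound (38.1%, odds ratio 3.32, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0469), among them iff-2, eif-3.C, eef-1G, eif-2Bbeta and eef-1A.1. Genes for mitochondrial respiration and mitochondrial ribosomes had 12 of 38 (31.6%, odds ratio 2.50, Fisher's exact test, adjusted p = 0.0469), with cox-6B, cox-5A, mrpl-28, mrpl-49 and cox-5B the highest. The mrpl-49 peak was also that of rpl-28. This list was matched by gene name, so respiratory genes under other names counted as other genes. One was ndua-8, which had an optimal peak and was named after its values were seen. Heat shock and chaperone genes had 10 of 24 (41.7%, odds ratio 3.87, Fisher's exact test, adjusted p = 0.0187), including hsp-90, cct-1, cct-8, hsp-110 and hsp-3. When each peak was given to its nearest start alone, 2 of the 24 chaperone genes were bound and the odds ratio was 0.714 (Fisher's exact test, adjusted p = 1), the other peaks having a closer neighbour. None of these 3 lists passed when any replicate was left out, with fewer peaks kept, although the odds ratios stayed above 1: 2.67 to 3.71 for translation factor genes, 2.69 to 3.22 for the mitochondrial genes and 2.37 to 3.82 for chaperone genes. Nor did they pass in the upper 50 percent of the optimal peaks (Fisher's exact test, adjusted p = 0.358 to 0.472), against the upper 50 percent of the candidates (0.153 to 0.375) or with the nearest start alone (0.0973 for the mitochondrial and 0.158 for translation factor genes). The wide window lost translation factor genes (Fisher's exact test, adjusted p = 0.0706), and the narrow one lost the mitochondrial (0.835) and chaperone genes (0.455).

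The synMuv and chromatin list, which includes lin-15B but is not limited to genes acting with it, had 9 of 19 bound (47.4%, 95% Wilson interval 27.3 to 68.3, odds ratio 4.87, Fisher's exact test, adjusted p = 0.0157). The strongest were lin-54 (in the promoter shared with rpl-12), lin-9 (score 74.3, summit 106 bp upstream, III 8904067), mrg-1 (48.0), lin-53 (47.1) and lin-38 (44.2). The mrg-1 peak was shared with spcs-2 and the lin-53 peak with nra-2. For lin-54, mrg-1 and lin-53 the start of the other gene was closer to the summit. lin-9, lin-53 and lin-54 encode subunits of the DREAM complex. The top-ranked peaks of single replicates covered 16.3% ± 1.28 (SD, n = 3) of the 45 annotated members, where 1.70% ± 0.0247 of all protein-coding genes were covered. Relative to genes with any peak in the same replicate list the odds ratios were 6.09, 7.91 and 7.53 (Fisher's exact test, two-sided, unadjusted p = 5.74e-04, 5.69e-05 and 2.06e-04). With fewer peaks or genes the call was lost while the odds ratio stayed above 1: without replicate 1 (odds ratio 3.03, Fisher's exact test, adjusted p = 0.276), without replicate 2 (2.20, adjusted p = 0.536), with the nearest start alone (3.69, adjusted p = 0.128) and in the upper 50 percent of the optimal peaks (3.73, adjusted p = 0.188). It was also lost against the upper 50 percent of the candidates (3.46, Fisher's exact test, adjusted p = 0.0854).

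Chemoreceptor genes were bound less often, 2 of 53 (3.77%, odds ratio 0.204, Fisher's exact test, adjusted p = 0.0469), the 2 being srh-16 and sri-5, each beside another gene. With any replicate left out and fewer peaks kept, the call was lost, while the odds ratio stayed low, between 0 and 0.221. It was also lost in the upper 50 percent of the optimal peaks (Fisher's exact test, adjusted p = 0.162), with the narrow window (0.167), against the upper 50 percent of the candidates (0.273) and with the nearest start alone (0.516). tRNA genes were also lower, 12 of 159 (7.55%, odds ratio 0.434, Fisher's exact test, adjusted p = 0.0276), and without the mitochondrial peaks 3 were bound. The tRNA call depended on the comparison: against all annotated genes 1.89% of tRNA genes and 1.98% of other genes were bound (odds ratio 0.957, Fisher's exact test, adjusted p = 1). The 1.89% again counts all 12 tRNA genes, of which 3 were bound by nuclear peaks, so it rests mostly on mitochondrial peaks. Relative to genes with a pooled peak the tRNA call was lost without replicate 2 (odds ratio 0.537, Fisher's exact test, adjusted p = 0.412), in the upper 50 percent of the optimal peaks (0.764, adjusted p = 1), with the wide window (0.801, adjusted p = 0.651) and with the nearest start alone (0.643, adjusted p = 0.619). The nearest-start rule was applied to protein-coding starts only. It left tRNA genes at 12 of 159, while the other bound genes fell from 395 to 281. The other 19 lists did not pass. They included cell cycle and DNA replication genes (5 of 21: knl-3, cdc-6, top-2, pcn-1 and zyg-1), meiotic chromosome genes (2 of 11: scc-2 and brc-1), small RNA pathway genes (1 of 11: mut-15), splicing genes (4 of 15: rsp-6, prp-8, snr-4 and prp-40), proteasome genes (3 of 16: rpn-3, rpt-2 and pas-4), histone genes (3 of 8: htz-1, his-67 and his-68), aminoacyl-tRNA synthetase genes (1 of 10: ears-2), collagen genes (1 of 10: col-71), homeobox genes (1 of 4: ceh-38) and microRNA genes (2 of 34: cel-mir-5595 and cel-mir-5549). No optimal peak was at a germ granule or germline RNA regulator (0 of 4), or at muscle (0 of 5), neuronal (0 of 6), intestinal (0 of 8), neuropeptide (0 of 9), nuclear hormone receptor (0 of 19), major sperm protein (0 of 1) or vulval signalling genes (0 of 1). For the germline list 0 of 4 allows a share of up to 49.0% (Wilson 95% bound), and 0 of all 36 annotated members allows up to 9.64%; the top-ranked peaks of each replicate also covered 0 of the 36. With the wide promoter window 2 of 7 were bound, cgh-1 and mex-1, named after their values were seen (odds ratio 2.61, Fisher's exact test, adjusted p = 0.513).

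**Figure D2:**
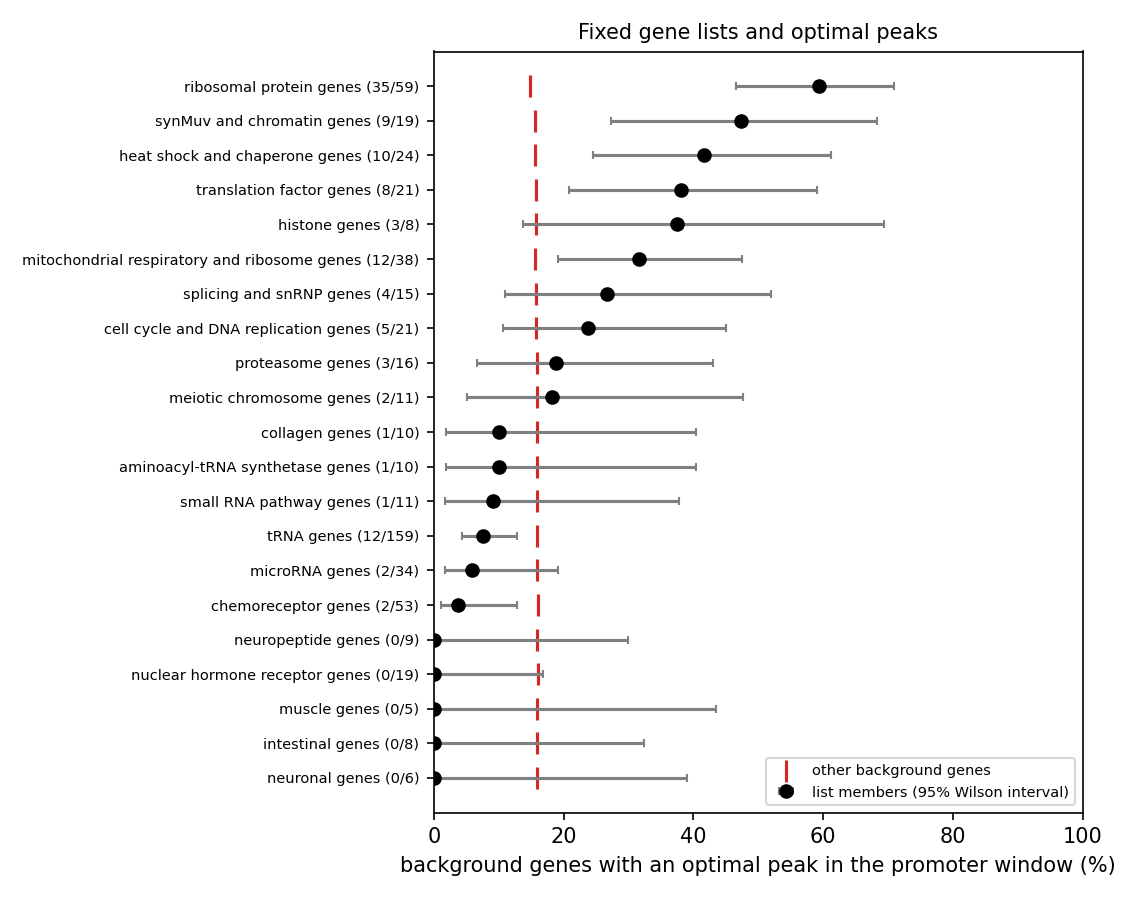
Percent of background genes with an optimal peak in the promoter window, for the fixed gene lists with at least 5 background genes, with bound and background counts in brackets; points are list members with 95% Wilson intervals and red ticks the other background genes. Ribosomal protein genes stand highest at 59.3%, against 14.8% of other genes.

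The loci tied to the transgene were looked at separately. An optimal peak lay at X 15725049 to 15725388 (score 51.1, rank 143), 904 bp upstream of lin-15B and outside the promoter window. A peak covered this summit in each replicate, at rank 2221 in replicate 1, 63 in replicate 2 and 256 in replicate 3. Inside lin-15B or within 1000 bp of it lay 4 pooled peaks, and 6, 10 and 5 peaks in the full lists of replicates 1, 2 and 3. A top-ranked peak of replicate 2, but not of replicates 1 and 3, lay in the lin-15B promoter window. The lists hold no reads, so binding at the native lin-15B locus could not be told apart from signal of the transgene copy. lin-15A had a pooled peak at rank 1306 that was not optimal, and the best ranks of a peak within 1000 bp of the gene or inside it were 3243, 156 and 6431 in replicates 1, 2 and 3, so that of replicate 2 was top-ranked. unc-119, the selection marker, had 0 pooled peaks, and 8, 1 and 3 peaks in the full replicate lists, with best ranks of 16518, 5492 and 1572.

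Optimal summits were rich in G and C and in CG-containing motifs. The median G+C content of 200 bp windows was 41.5% for optimal and 35.5% for candidate peaks, a difference of 6 points (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest they can give). The replicates gave 40.0% ± 1.32 (SD, n = 3) for their top-ranked peaks, above the rest of the list in 3 of 3. The tetramer CGCG was in 63.4% of optimal and 20.5% of candidate windows (odds ratio 6.71, Fisher's exact test, two-sided, adjusted p = 9.86e-69 over 10 motifs). The E2F element TTSSCGC, bound by E2F proteins of the DREAM complex, was in 19.6% against 6.97% (odds ratio 3.25, Fisher's exact test, adjusted p = 2.11e-14), and the top-ranked peaks of the replicates gave 16.5% ± 2.03 (SD, n = 3), higher in 3 of 3. The SP1-like box GGGCGG (9.40% against 3.78%, Fisher's exact test, adjusted p = 5.59e-06) and the GA repeat GAGAGA (22.7% against 14.5%, adjusted p = 8.66e-05) were also higher; stratified by G+C content against all candidates the GA repeat did not pass (odds ratio 1.18, Mantel-Haenszel test, adjusted p = 0.255), while the SP1-like box did (1.62, adjusted p = 0.0226). The GATA element TGATAA was lower, 12.01% against 18.4% (odds ratio 0.605, Fisher's exact test, adjusted p = 0.00219), a call that was lost when candidates were stratified by G+C content (odds ratio 0.773, Mantel-Haenszel test, adjusted p = 0.16). The CHR element TTYGAA, the other DREAM site, did not pass (56.1% against 53.1%, Fisher's exact test, adjusted p = 0.312), nor did the E-box, the CCAAT box, the T-block and the CG dinucleotide.

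Against candidate peaks in promoters, stratified by G+C content, CGCG (odds ratio 2.62) and the E2F element (1.71) stayed higher. The CHR element (1.57) and the T-block (1.45) passed as higher there, as they did against all candidates stratified in the same way (1.66, 95% interval 1.34 to 2.07, and 1.77, 1.41 to 2.21). Unstratified, the T-block also passed without replicate 2 (1.74) and without replicate 3 (1.60). Their direction depended on the comparison, since with 100 bp windows and no stratification both were lower (0.771 and 0.582). In the top-ranked peaks of the replicates the CHR element was in 51.8% ± 2.37 (SD, n = 3) of windows against 53.96% ± 1.68 in the rest of each list, lower in 3 of 3, and the T-block was higher in 1 and lower in 2. The SP1-like box (1.11), the GA repeat (0.918) and the GATA element (0.749) did not pass against the stratified promoter candidates.

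**Figure D3:**
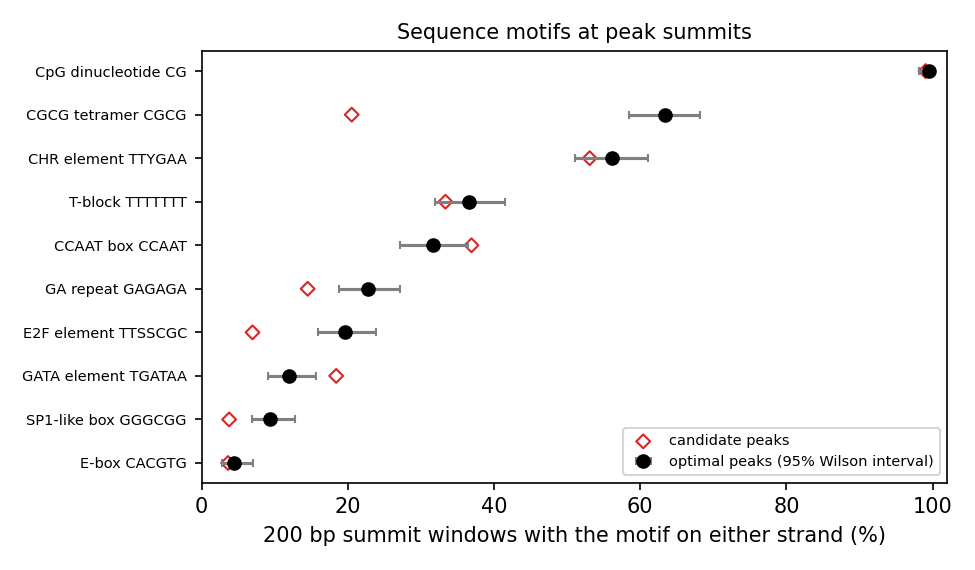
Percent of 200 bp summit windows that contain each motif on either strand, for optimal peaks (points with 95% Wilson intervals) and candidate peaks (open red diamonds). CGCG shows the widest gap, 63.4% against 20.5%.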

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

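The tests of the mitochondrial peaks in this part were chosen after the result was seen. In data outside the nuclear comparisons, 18 optimal peaks lay on mitochondrial DNA, a sequence no candidate peak touched. The pattern differed by replicate, with 20, 0 and 29 mitochondrial peaks in the lists of replicates 1, 2 and 3. Binding of the same mitochondrial sites in every replicate cannot be told apart from a technical source, because the replicate with 0 peaks may lack mitochondrial reads altogether and the lists hold no reads to show it. An excess of mitochondrial DNA in some libraries would give peaks over most of that genome, and they covered 48.4% in replicate 1 and 63.6% in replicate 3, one below and one above the bound of 50 percent, so this stays open too. For comparison, the same lists covered 10.9% and 11.4% of the nuclear genome. No biological explanation beyond binding of the same mitochondrial sites was weighed.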

How the results depend on the processing

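Alternatives added after seeing the data were leaving out mitochondrial peaks, giving each peak to its nearest protein-coding start alone, removing peaks at promoters of the fixed lists for the X share, and stratifying all candidates by G+C content, the last chosen before its own values were computed. The promoter share, the X share and the G+C difference kept their direction and their side of the threshold under each alternative run for them; the promoter share ranged from 53.0% to 85.2%, the X share from 3.99% to 10.9%. The centre share kept both against candidate backgrounds, but against random positions it turned to the other side (34.5% against 33.0%, Fisher's exact test, p = 0.56), which follows from the background alone. With the upper 50 percent of the optimal peaks, the number was 192, recovery 74.1%, overlap 58.8% and the lists past the threshold 1 in place of 7. Leaving out each replicate gave 162 to 179 peaks, which follows from requiring the peak in both other lists, and 1 to 3 lists past the threshold. The overlap is then that of the remaining pair, 44.9% to 50.4% as given above, and adds no further test. With 2 times as many top peaks recovery was 76.8% and overlap 35.1%; with 50% reciprocal overlap and with summits within 100 bp overlap was 44.3% and 43.6%. Lists past the threshold numbered 4 with the narrow promoter window, 2 against the upper 50 percent of candidates, 1 with the nearest start alone and 9 against all annotated genes, where cell cycle, splicing and nuclear hormone receptor genes gained the call and tRNA genes lost it. With the nearest start alone the odds ratio of chaperone genes turned to 0.714. Smaller sets of bound genes leave less power in several of these, and the cause was otherwise not tested. Motifs past the threshold numbered 8 in place of 5 with 100 bp windows, where the CHR element (odds ratio 0.771) and the T-block (0.582) turned lower; the GA repeat turned to 0.918 against promoter candidates stratified by G+C content, and the cause was not tested. Among single lists, motifs and named peaks, 401 values under an alternative kept their direction and their side of the threshold, or for named peaks their count of replicates, although sizes changed; 41 lost the threshold, 12 gained it, 8 moved and 35 turned direction. Of these 35, 31 passed in neither setting. In the upper 50 percent of the optimal peaks the odds ratio turned to 1.03 for small RNA pathway genes, 1.14 for aminoacyl-tRNA synthetase genes, 0.733 for splicing genes, 0 for homeobox genes and 0.944 for the CG dinucleotide. Leaving out each replicate gave 1.12 to 1.17 for small RNA pathway, 1.25 to 1.30 for synthetase, 0 to 1.80 for splicing, 0 to 3.91 for histone and 0 for homeobox genes, and 0.865 for the CG dinucleotide without replicate 2. The wide window gave 2.61 for germline, 1.87 for small RNA pathway and 0.929 for homeobox genes, and the narrow one 0.478 for cell cycle and 1.60 for collagen genes. Against the upper 50 percent of candidates meiotic genes had 0.851; against all annotated genes small RNA pathway genes had 1.06, synthetase genes 1.60 and homeobox genes 0.619; with the nearest start alone cell cycle genes had 0.827. Stratified by G+C content the CG dinucleotide had 0.783 against promoter candidates and 0.986 against all, and the E-box 0.942 against all. The cause of these turns was not tested. No finite odds ratio was obtained for the CG dinucleotide without replicate 1, without replicate 3 or without mitochondrial peaks, nor for the vulval, sperm protein and transgene lists under some windows or backgrounds. The ce10 list held 351 peaks, and the ce11 pool had 351 peaks at or above the lowest ce10 optimal score. No paired analysis was possible because there is only 1 group. Depth is unknown, so its effect on the replicates was not tested.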

Other observations

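The comparison of non-coding genes, the X share without listed genes and the tests of tissue genes, of single replicates and of other housekeeping classes in this part were chosen after the results were seen; stratification of all candidates by G+C content was also chosen after the patterns were seen, but its predictions were set before the stratified odds ratios were computed. Genes for small nucleolar RNAs, which guide the modification of ribosomal RNA, stood near a larger share of optimal than of candidate peaks: 15 of 365 nuclear optimal peaks (4.11%) and 73 of 8232 candidate peaks (0.887%) had a snoRNA start in the promoter window (odds ratio 4.79, Fisher's exact test, two-sided, adjusted p = 1.47e-05 over 4 non-coding classes). Of these 15 peaks, 9 also lay in the promoter window of a protein-coding gene, among them those of rps-12, rps-26, rpl-7A and rps-10. Small nuclear RNA genes had 4 of 365 against 13 of 8232 (odds ratio 7.01, Fisher's exact test, adjusted p = 0.0098). Of the 18 sls-2 genes, which encode the SL2 spliced leader, 5 had an optimal peak within 500 bp and 16 a pooled one. MicroRNA genes (2 of 365) and nuclear tRNA genes (3 of 365) did not pass (Fisher's exact test, adjusted p = 0.379 for both).

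The frequent binding at ribosomal protein promoters is not accounted for by G+C content of the summit windows alone, since the odds ratio stratified by it was 6.75 (95% interval 3.88 to 11.8). One replicate alone does not carry it, since the lowest replicate still bound 30.8% of the annotated members. Other housekeeping genes (proteasome, aminoacyl-tRNA synthetase and splicing) were bound more often than the remaining annotated genes, 8 of 107 (7.48%) against 1.78% (odds ratio 4.46, Fisher's exact test, two-sided, p = 7.29e-04). Among genes with a pooled peak 8 of 41 did not pass (19.5%, odds ratio 1.41, Fisher's exact test, two-sided, p = 0.375). These classes all came from lists that had not passed. Translation factor (8 of 21), mitochondrial (12 of 38) and chaperone genes (10 of 24) had passed but were left out of this comparison. Whether a general preference is part of the pattern therefore stays open. Ribosomal protein genes exceeded the proteasome, synthetase and splicing classes among genes with a pooled peak (odds ratio 6.02, Fisher's exact test, two-sided, p = 8.55e-05) and among all annotated ones (10.1). That comparison cannot show whether a general preference is the whole of the pattern. It set the highest list in these data against classes that had not passed and were not matched for transcription. Recovery of highly transcribed or accessible promoters stays open, because neither transcription nor a second tagged protein was analysed here and the 1 of 234 annotated muscle, intestinal and collagen genes bound (0.427%) decides nothing where each tissue is only part of the animal.

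For the CG-rich motifs, G+C content was weighed in the same way. Stratified by G+C content against all candidates, the odds ratio was 2.45 for the E2F element (95% interval 1.87 to 3.22) and 5.21 for CGCG (4.14 to 6.57), so base composition in bins of 5 percent did not remove either. Against promoter candidates stratified in the same way they were smaller, 1.71 and 2.62. The results for these motifs are not separate, since some sequences that match TTSSCGC contain CGCG. The E2F element was not tested apart from CGCG. Presence of these elements because LIN-15B sits with E2F proteins at DREAM sites may be one reading, and it was not tested, as no lists of other DREAM subunits were analysed here.

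The low X share stayed when peaks at promoters of the fixed lists were removed, at 10.9% against 17.99% of candidates (Fisher's exact test, two-sided, p = 0.00216).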
